A study of Mus musculus with 21 samples.

How the data were processed

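Gene expression was measured on 21 Illumina bead arrays, 3 for each of 7 stages of follicle development in CD1 mice. Per the labels, RNA was purified with a kit for small samples from pooled ovaries or follicles of a stage, amplified in 1 round to labelled RNA and hybridised. The arrays hold 25697 probes.

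The signal table gives intensity per probe and array, which per the file headers is the average bead signal; as deposited it was neither background corrected nor normalised, and medians differed between arrays. Beside it stands a detection p-value per probe and array, which per the file headers tests the signal against the negative control beads of that array. A second table holds the authors' values on the log2 scale. The authors name limma among their tools without a version. Their transformation, normalization and filter on probes are not stated. The medians of their columns lay between 7.71 and 7.74. Their gene-centred values correlated at 0.862 to 0.908 with the gene-centred log2 values used here, taken after background correction and quantile normalization. The correlation was across genes, which are not independent replicates.

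Samples were grouped by their titles. Some labels disagree with them. PREANTRAL repeat 2 has the source name, day and diameter of an antral sample, PRIMARY repeat 3 carries the stage tag PMD3, and ANTRAL repeat 2 is described as repeat 3. The tissue of TLS repeat 2 and of PRIMARY repeat 3 is given as ovary. The treatment protocol reads that no treatment was given, whereas the source names of ANTRAL name pregnant mare serum gonadotropin. Among the columns of signal, 2 antral arrays share 1 name, so that they have no repeat number and are called ANTRAL repeat a and repeat b.

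The 2 detection columns of these antral arrays, which share a name as well, were not used here. Each of their probes was given the mean detection p that the probe of the same rank of signal has on the 19 other arrays. The step was tested by treating each of those 19 arrays in this way. It shared 96.4% to 99.9% of the detection calls with the array's own p-values, and the background mean moved by at most 2.09 signal units. Both the lowest share and the largest move were those of ANTRAL repeat 1, the only antral array whose own p-values were used. The step gave repeats a and b 13222 detected probes each, against 12363 on repeat 1 by its own p-values. It may therefore call detection too often on antral arrays. This step was chosen after the data were seen.

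Signals were background corrected and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p, adds an offset of 16 and takes log2. Of the probes, 21857 had 1 gene symbol in the array's annotation and 3840 had none, which left 15548 symbols. The Entrez identifiers of 21846 probes were found in the RefSeq table, and no symbol had to be updated. Probes were kept if their detection p was under 0.05 on at least 3 arrays, which 15923 were, 13691 of them with a symbol. Each gene was represented by its probe with the highest mean over all arrays, without regard to stage. This gave 10112 genes, of which 2536 had a choice of probes. Unnamed probes were left out of the tests.

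One limma model with a mean per stage was fitted to all 21 arrays, with empirical Bayes moderation of the variance. Each stage was compared with the one before it and ANTRAL with PRIMARY, all two-sided, with the Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. A moderated F test asked whether a gene differed over the 7 stages. With 3 arrays per stage, the number of arrays limits the precision.

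For 29 gene lists of cell types, pathways and processes, 455 of 555 memberships were named on the array. They cover oocyte growth, early germ cell regulators, meiotic prophase, granulosa cells, theca and interstitial cells, stroma and smooth muscle, endothelium, leukocytes, erythroid cells, surface epithelium, steroidogenesis, gonadotropin response, ovulatory response, cell cycle, stress and immediate early genes, apoptosis and atresia, cytosolic ribosomal proteins, and 12 lists of metabolism. The metabolic lists are glycolysis and lactate, pyruvate dehydrogenase and TCA cycle, oxidative phosphorylation, the pentose phosphate pathway, purine and pyrimidine metabolism, cholesterol synthesis, fatty acid oxidation, fatty acid synthesis, glutathione and peroxide metabolism, one-carbon and serine metabolism, and amino acid transporters. Each list was tested in each comparison with camera of limma, which compares the list with the other genes, with a preset correlation of 0.01 between genes. The p-values were adjusted over all 203 tests. The tests were repeated with an estimated correlation and with fry, which asks whether the members move one way on balance without comparing them with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. Some genes sit in more than 1 list.

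Genes named by the text followed a rule with 4 parts. The first is a panel of 20 genes of oocyte, granulosa and theca cells, of which 17 were on the array. The second is, per comparison, the 6 rising and 6 falling genes with the largest fold change among those past the threshold, detected on all arrays of both stages and with replicates that do not overlap. The third is up to 2 rising and 2 falling genes with the smallest adjusted p among those detected on no array of 1 stage and on all of the other. The fourth is up to 4 members of each list past its threshold with the largest moderated t in the list's direction. Gene models without a name were left out of the second and the third part. Genes of the third part are given as a bound, for which the dim stage took, per array, the higher of the lowest detected signal and the probe's own value. List medians were also computed with such members at their bound. Of 79 list results past the threshold 51 had such a member, 13 medians moved by more than 0.1, and none changed sign.

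The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were no background correction, median scaling in place of quantile normalization, the authors' values, no filter on dim probes, a strict filter (detection p under 0.01 on all arrays of a stage), the mean of a gene's probes, trend and robust variance moderation, array weights, the repeat number as a block, an adjusted p under 0.01, each array left out in turn, the 2 stages of a comparison alone, and a limma test against a 1.2-fold change. Median scaling aligned the arrays on the median of all 25697 probes, of which 48.1% to 54.3% were detected per array. That median lies near the background. On TLS repeat 1 the median signal was 91.5, below the lowest detected signal of 92.2. As 2 antral arrays have no repeat number, the repeat block was run without them, a form chosen after the data were seen. A block for the slide was not run, since the files do not name the slides. Other alternatives chosen after the data were seen left out 2 deviating arrays together, used the repeat block on the authors' values, and tested gene families.

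The procedure was tested on simulated data of the same size, in which each gene varied independently with its own measured spread, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold per comparison among 10112 genes. Of the 4-fold changes, between 95.5% (ANTRAL against PRIMARY) and 100% were found. Of the 2-fold changes, between 56.7% (ANTRAL against PREANTRAL) and 77.6% (PMD4 against PMD3, ANTRAL against PRIMARY) were found. Of the 1.5-fold changes, it was between 16.4% (PREANTRAL against MLS) and 32.8% (MLS against TLS). False calls made up at most 7.87% of the calls (ANTRAL against PREANTRAL). Every comparison was simulated from the same means and spreads with 1 random draw, so these differences between comparisons reflect the draw and not the stages. Recovery with many more genes changed was not simulated. When the oocyte growth list was shifted by 0.5 on the log2 scale, it was called in each of the 7 comparisons, and 1 list without a shift was called in ANTRAL against PREANTRAL. Here the p-values were adjusted over the 29 lists of a comparison, not over all 203 tests. As the simulated genes varied independently, this cannot show how the list test behaves with correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.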

Results

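Gene expression was measured on 21 bead arrays, 3 for each of 7 stages of mouse ovarian follicle development in CD1 mice. The earliest stages, PMD3 and PMD4, were whole ovaries taken on postnatal day 3 and day 4, when most follicles are primordial. The later stages were follicles isolated from ovaries and sorted by diameter. PRIMARY follicles measured 70 to 90 µm on day 10, two-layer secondary (TLS) follicles 100 to 130 µm on day 12 and multilayer secondary (MLS) follicles 150 to 180 µm on day 16. PREANTRAL follicles measured 200 to 300 µm on day 18. ANTRAL follicles measured 400 to 600 µm on day 20 and came from mice given pregnant mare serum gonadotropin, a hormone preparation with follicle-stimulating activity, so that treatment and stage could not be separated. Between 12363 and 13953 probes were detected per array, or 48.1% to 54.3% of the probes, and the median signal ran from 91.5 to 143. With 3 arrays per stage, the number of arrays limits the precision. Nothing in the labels says that the 3 samples of a stage came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Levels are given on the log2 scale as the mean of 3 arrays with the standard deviation (SD).

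The first question was how far expression differs among the stages at all. Of 10112 genes tested, 6735 differed over the 7 stages at an adjusted p under 0.05, or 66.6%. Gdf9 and Bmp15, which encode growth factors secreted by the oocyte, peaked at PRIMARY with levels of 14.89 ± 0.09 and 13.38 ± 0.04. Figla, a regulator of early oocyte genes, stood at 10.85 in PMD3 and at 5.22 in ANTRAL. Inhba, which encodes the inhibin and activin beta-A subunit of granulosa cells, stood highest in ANTRAL at 14.19 ± 0.35. Star, whose product carries cholesterol into mitochondria for steroid synthesis, was detected only in ANTRAL at 7.92 ± 0.15. Ccnd2, which drives granulosa cell division, lay between 10.18 and 11.47 and passed in no comparison with all arrays kept. PMD3 repeat 2 and TLS repeat 2 deviate from their stages, and with both left out Ccnd2 fell by 1.10 (log2) from PMD4 to PRIMARY and by 0.82 from PREANTRAL to ANTRAL. It then rose by 1.41 from TLS to MLS, against 0.65 with all arrays. Of the genes that differed, 1714 had their highest mean in ANTRAL, 1265 in PRIMARY and 1254 in PMD3, and 304 had it in MLS. The first principal component held 37.3% of the variance and the second held 28.1%. TLS repeat 1 had a mean correlation of 0.980 with MLS and of 0.972 with the other TLS arrays. TLS repeat 3 had one of 0.981 with PRIMARY and of 0.973 with the other TLS arrays. PMD3 repeats 1 and 3 had one of 0.986 with PMD4 and of 0.980 with the other PMD3 arrays. These means within a stage include the deviating repeat 2.

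**Figure D1:**
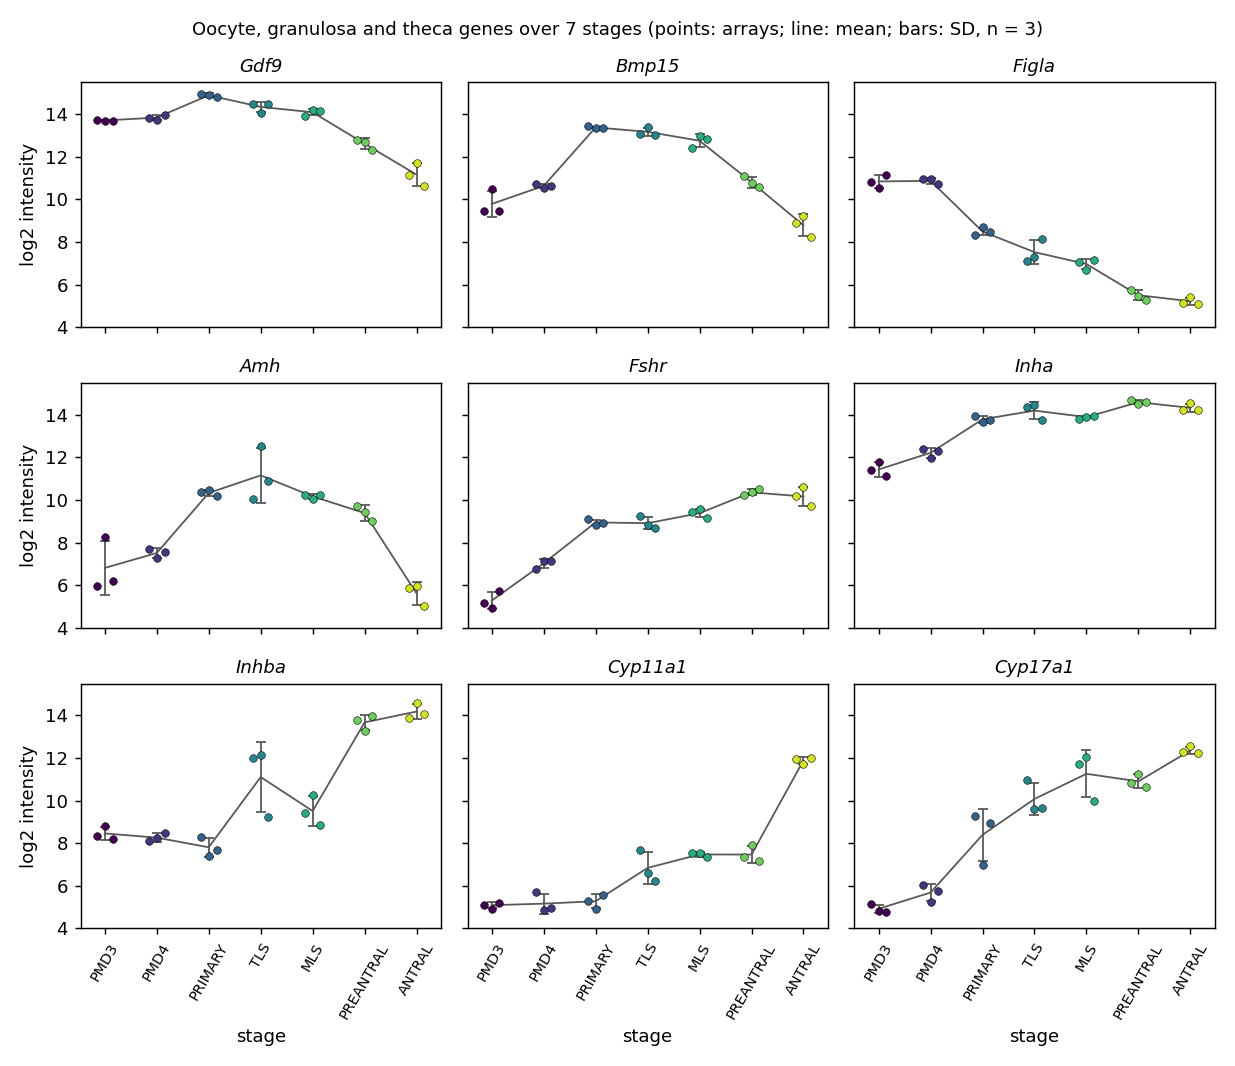
Log2 expression (y axis) of 9 genes of oocyte, granulosa and steroid-producing cells at the 7 stages (x axis), with points for the arrays, a line through the stage means and bars of 1 SD, n = 3 arrays per stage. Gdf9 peaked at 14.89 in PRIMARY and Cyp11a1 reached 11.89 in ANTRAL.

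**Figure D2:**
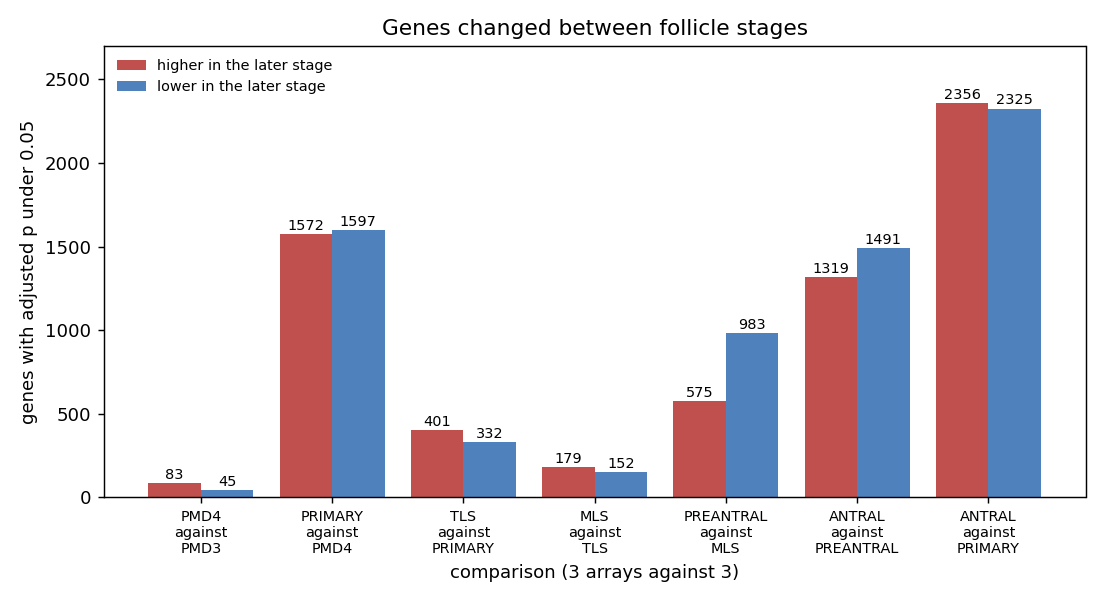
Number of genes (y axis) that rose or fell at an adjusted p under 0.05 in each comparison (x axis), of 10112 tested. The counts ran from 128 genes for PMD4 against PMD3 to 4681 genes for ANTRAL against PRIMARY.

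**Figure D3:**
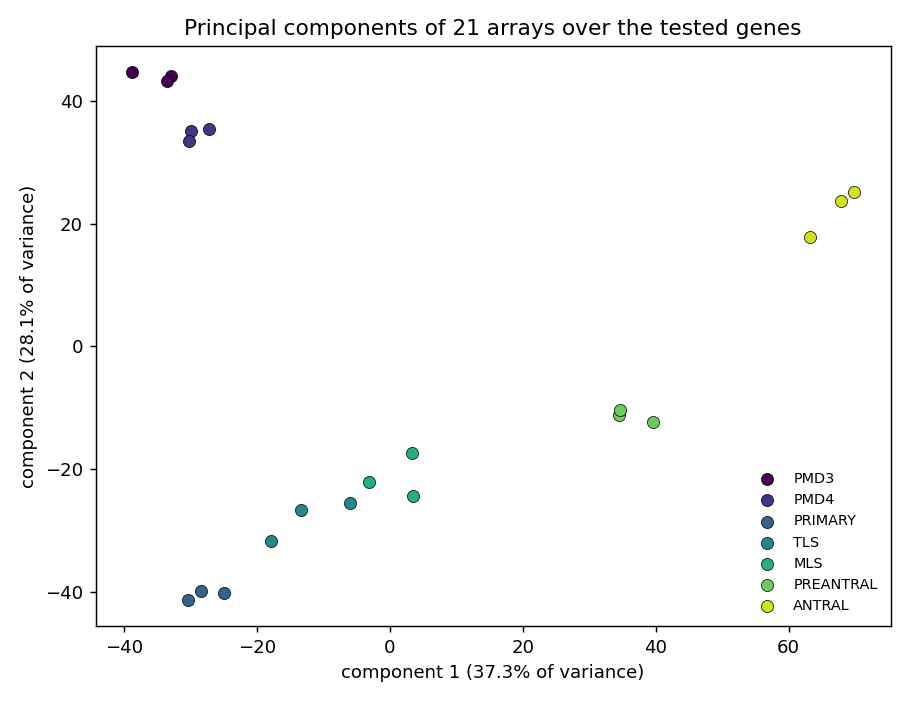
The 21 arrays on the first principal component (x axis, 37.3% of the variance) and the second (y axis, 28.1%), with 1 colour per stage, 3 arrays each.

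PMD4 was compared with PMD3 to ask what changes between whole ovaries 1 day apart. Hsd17b1, which converts estrone to estradiol in granulosa cells, rose 3.01-fold, from 10.28 ± 0.42 to 11.87 ± 0.05 (adjusted p = 0.000114). Arl16, a small GTPase, rose 3.51-fold to 9.09 ± 0.10 (adjusted p = 0.000109). Gstm6, a glutathione transferase, was 2.66-fold lower at 8.31 ± 0.23 (adjusted p = 0.00208), and Acsm3, an enzyme of medium-chain fatty acids, was 2.53-fold lower. Fshr, the receptor of follicle-stimulating hormone, rose 3.36-fold, a call that was lost with the authors' values. Its mean in PMD3 was 5.28 with detection on only 2 of 3 arrays, so the fold rests partly on background. Musk, a receptor kinase, was detected in all PMD3 arrays and in no PMD4 array, and was at least 2.20-fold lower. For a gene undetected in 1 stage, such a bound compares the bright stage's mean with the dim stage's mean of, per array, the higher of the lowest detected signal and the probe's own value. Gdf9 (adjusted p = 0.826), Bmp15 (adjusted p = 0.126) and Amh (adjusted p = 0.589), the last encoding anti-Müllerian hormone, did not pass. Without PMD3 repeat 2 Bmp15 passed with a log2 fold change of 1.19, against 0.85 with it. Amh moved from 0.70 to 1.44 without that array, and passed only when TLS repeat 2 was left out as well.

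Of 10112 genes, 128 changed between PMD3 and PMD4, 83 up and 45 down, and 1355 had an unadjusted p under 0.05. Of 29 gene lists, 8 stood higher and 1 lower in PMD4 than the other genes. The erythroid list rose by a median of 0.91, with 2 of 4 genes up and 3 adjusted over the list alone. The stress and immediate early list had a median of 0.95, with 2 of 15 genes up and 9 adjusted over the list alone (adjusted p = 0.0850 with an estimated correlation). In the granulosa cell list, 3 of 19 genes rose and 8 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.182 with an estimated correlation). Steroidogenesis genes had a median of 0.20, with 1 of 10 up and 2 adjusted over the list alone (adjusted p = 0.0850 with an estimated correlation). With its undetected members at their bound the median of that list was 0.07. Another 5 lists passed: oocyte growth with a median of 0.18 and 1 of 22 genes up, and endothelium (0.28), cell cycle (0.16), pyrimidine synthesis (0.20) and early germ cell regulators (-0.26), each with 0 genes past the threshold. All 5 were lost with an estimated correlation (adjusted p = 0.0940 to 0.531), and all but oocyte growth without PMD4 repeat 3, where their medians were 0.32, 0.14, 0.21 and -0.31. Without PMD3 repeat 1 endothelium (0.35), cell cycle (0.16) and pyrimidine synthesis (0.18) were lost, and without PMD3 repeat 3 endothelium (0.20), cell cycle (0.21) and early germ cell regulators (-0.27). Early germ cell regulators were also lost with median scaling (-0.13) and without PMD3 repeat 2 (-0.18) and PMD4 repeat 1 (-0.19), pyrimidine synthesis without PMD4 repeat 1 (0.15), and oocyte growth, endothelium and early germ cell regulators with fry. The count for PMD4 against PMD3 fell with each array of these stages left out. It was 86 without PMD3 repeat 1, 44 without PMD3 repeat 2 and 104 without PMD3 repeat 3. It was 36 without PMD4 repeat 1, 32 without PMD4 repeat 2 and 73 without PMD4 repeat 3. The count was 210 without TLS repeat 2, which entered through the shared variance. Of the genes changed, 64.8% rose, against 77.0% with median scaling, 54.4% without background correction and 48.6% with the authors' values.

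PRIMARY was compared with PMD4 to ask how isolated primary follicles differ from the ovary in which follicles begin to grow. Bmp15 rose 6.71-fold, from 10.64 ± 0.08 to 13.38 ± 0.04 (adjusted p = 3.93e-08), and Gdf9 rose 2.07-fold from 13.84 ± 0.12 (adjusted p = 0.000433). Amh rose 7.05-fold to 10.33 ± 0.14 (adjusted p = 0.000195) and Fshr rose 3.79-fold to 8.95 ± 0.13 (adjusted p = 7.16e-07). Among the largest rises were Obox7, an oocyte homeobox gene, at 22.1-fold and Cldn11, which encodes a tight-junction protein, at 22.0-fold. Igf2, a fetal growth factor, was 38.1-fold lower, having stood at 12.82 ± 0.05 in PMD4 and at 7.57 ± 0.36 in PRIMARY. Upk3b, a marker of the ovarian surface epithelium, was 49.2-fold lower (adjusted p = 1.24e-12). Crygb, a lens crystallin gene, was at least 23.5-fold lower. This comparison sets whole ovaries against isolated follicles, so stage and tissue could not be separated.

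Between PMD4 and PRIMARY 3169 genes changed, 1572 up and 1597 down, and 1477 changed by at least 2-fold. In the oocyte growth list 14 of 22 genes rose and 2 fell, also adjusted over the list alone, with a median of 0.79 (adjusted p = 0.368 with an estimated correlation). Rfpl4, Bcl2l10 and H1f8, all of the oocyte, rose 4.72-fold, 4.34-fold and 3.70-fold. In the granulosa cell list 10 of 19 genes rose, the same number adjusted over the list alone, with a median of 0.66 (adjusted p = 0.173 with an estimated correlation). Ihh and Dhh, which encode hedgehog signals sent by granulosa cells, rose 9.13-fold and 4.25-fold. Steroidogenesis genes rose by a median of 0.64, 5 of 10 of them and 5 adjusted over the list alone (adjusted p = 0.110 with an estimated correlation), a call lost with the authors' values (median 0.13). In the list of early germ cell regulators 5 of 10 genes fell, and 7 fell and 1 rose adjusted over the list alone, with a median of -0.67 (adjusted p = 0.0756 with an estimated correlation). Sohlh1 and Figla, which switch on early oocyte genes, were 10.5-fold and 5.20-fold lower. Amino acid transporters had a median of 0.31, with 8 of 17 genes up and 2 down, and passed, though not without PMD4 repeat 3 (median 0.40), with median scaling (0.28), with the authors' values (0.07), with PMD3 repeat 2 and TLS repeat 2 left out or with an estimated correlation (adjusted p = 0.110). Meiotic prophase genes passed with a median of -0.19 and 3 of 7 down, though not without PRIMARY repeat 2 (median -0.15), with no filter (0.01), with the same 2 arrays left out or with an estimated correlation (adjusted p = 0.135).

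Genes of 5 other cell types stood lower in PRIMARY than in PMD4, whereas the theca and interstitial cell list did not pass, with a median of 0.08, 2 of 10 genes up and 2 down, also adjusted over the list alone (adjusted p = 0.877). All 12 endothelial genes fell, also adjusted over the list alone, with a median of -1.88 (adjusted p = 1.88e-10). Esam, Flt1 and Emcn, found in vessel walls, were 8.79-fold, 7.83-fold and 6.06-fold lower. Of 10 leukocyte genes 9 fell, also adjusted over the list alone, by a median of -1.60. Laptm5, a lysosomal gene of blood cells, was 11.5-fold lower. Of 8 surface epithelium genes 6 fell and 1 rose, also adjusted over the list alone, with a median of -2.22. Of 4 erythroid genes 3 fell, also adjusted over the list alone, with a median of -2.44. In the list of stroma and smooth muscle 12 of 17 genes fell and 1 rose, also adjusted over the list alone, with a median of -1.76 (adjusted p = 0.103 with an estimated correlation). The matrix genes Ogn and Dcn were 7.91-fold and 6.53-fold lower. With undetected members at their bounds the medians were -1.63 for endothelium, -1.12 for leukocytes, -1.92 for surface epithelium and -1.84 for the erythroid list.

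TLS was compared with PRIMARY to ask what changes as follicles gain a second granulosa layer. Emcn rose 4.71-fold, from 6.45 ± 0.20 to 8.69 ± 0.46 (adjusted p = 1.01e-06), and Flt1, a receptor of vascular growth factor, rose 6.93-fold. Ogn rose 6.02-fold to 11.17 ± 0.13 (adjusted p = 2.58e-06). Upk3b rose 9.75-fold to 8.28 ± 0.44, after its low level in PRIMARY. Cxcl12, a chemokine of stromal cells, rose 5.67-fold. Tcf21, a transcription factor of stromal and theca precursors, rose 2.69-fold (adjusted p = 0.00123). Inhba rose 9.85-fold, although its level varied widely over the TLS arrays (11.11 ± 1.65) and its call was lost when the variance came from these stages alone. Without TLS repeat 3 its log2 fold change was 4.25. Smc1b, a cohesin gene of meiosis, was 2.48-fold lower (adjusted p = 0.000111), and Drp2, a dystrophin relative, was 4.52-fold lower. The oocyte genes Gdf9 (adjusted p = 0.120) and Zp3 (adjusted p = 0.0805), the latter encoding a protein of the egg coat, did not pass, but Zp3 passed without TLS repeat 3, with a log2 fold change of -0.75 in place of -0.62, and with median scaling at -0.90.

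Between these stages 733 genes changed, 401 up and 332 down. Of 12 endothelial genes 9 rose and 11 adjusted over the list alone, with a median of 1.39 (adjusted p = 4.57e-16). Of 17 genes of stroma and smooth muscle 9 rose and 11 adjusted over the list alone, with a median of 1.08 (adjusted p = 2.15e-10). In the theca and interstitial cell list 4 of 10 genes rose and 6 adjusted over the list alone, with a median of 0.74 (adjusted p = 5.15e-05). In the surface epithelium list 2 of 8 genes rose and 4 adjusted over the list alone, with a median of 0.56. At their bounds the medians were 1.16 for endothelium and 0.33 for surface epithelium. The leukocyte list did not pass, with a median of 0.33 and 1 of 10 genes up, also adjusted over the list alone (adjusted p = 0.0912), but it passed with median scaling (median 0.29) and with fry. Of its 10 genes 8 were undetected in PRIMARY or TLS. The stress and immediate early list rose by a median of 0.78, with 3 of 15 genes up and 6 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Oocyte growth genes fell by a median of -0.55, 4 of 22 of them and 14 adjusted over the list alone (adjusted p = 0.240 with an estimated correlation). Gonadotropin response genes had a median of 0.42, with 4 of 9 up, also adjusted over the list alone (adjusted p = 0.0856 with an estimated correlation). Granulosa cell genes had a median of 0.27 with 2 of 19 up (adjusted p = 0.288 with an estimated correlation), a call lost without TLS repeat 2, where the median was 0.13. Steroidogenesis genes had a median of 0.39 with 2 of 10 up. Early germ cell regulators and meiotic prophase had medians of -0.66 and -0.51 with 3 of 10 and 2 of 7 genes down (adjusted p = 0.0672 and 0.0558 with an estimated correlation).

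In TLS against PRIMARY 4 metabolic lists passed as well, with at most 1 gene each past the threshold. Their medians were 0.19 for glycolysis and lactate, 0.18 for pyruvate dehydrogenase and TCA cycle, 0.20 for oxidative phosphorylation and 0.26 for fatty acid synthesis (adjusted p = 0.0940 to 0.256 with an estimated correlation). All 4 calls were lost with median scaling, where the medians were 0.01, -0.07, -0.07 and 0.12. Without TLS repeat 3 the calls of glycolysis, the TCA cycle and fatty acid synthesis were lost (medians 0.19, 0.16 and 0.39), and without TLS repeat 2 that of oxidative phosphorylation (0.10). Glycolysis and fatty acid synthesis were also lost without PRIMARY repeat 2 (0.19 and 0.32), PRIMARY repeat 3 (0.13 and 0.28) and TLS repeat 1 (0.16 and 0.28), and the TCA cycle without PRIMARY repeat 1 (0.19). The authors' values ended the calls of glycolysis (0.11) and fatty acid synthesis (0.13), and no background correction that of glycolysis (0.16). The count for TLS against PRIMARY was 474 without PRIMARY repeat 1, 381 without PRIMARY repeat 2, 415 without PRIMARY repeat 3 and 438 without TLS repeat 2. Of the genes changed 54.7% rose, against 26.3% with median scaling and 41.9% with the authors' values, and median scaling moved the median of all genes from -0.02 to -0.16.

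MLS was compared with TLS to ask what changes as secondary follicles add granulosa layers. Pebp4, a member of a phospholipid-binding family, was detected in all MLS arrays and in no TLS array, and was at least 9.24-fold higher (adjusted p = 7.16e-08). Csrp1, a cytoskeletal LIM-domain gene, was detected in all TLS arrays and no MLS array, and was at least 11.9-fold lower (adjusted p = 0.000515). Rhox8, a homeobox gene of gonadal somatic cells, was 3.24-fold lower, having stood at 8.11 ± 0.25 in TLS and at 6.41 ± 0.07 in MLS (adjusted p = 7.49e-05). Ccng2, which slows the cell cycle, was 3.12-fold lower (adjusted p = 0.00855). Slc38a5, a glutamine transporter, rose 3.57-fold to 11.99 ± 0.32, although its call and that of Ccng2 were lost when the variance came from these stages alone. Inhba (adjusted p = 0.0957), Amh (adjusted p = 0.340) and Fshr (adjusted p = 0.284) did not pass. Inhba had a log2 fold change of -1.60, and without TLS repeat 3 it passed with -2.55. Amh moved from -0.99 to -0.29 without TLS repeat 2.

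From TLS to MLS 331 genes changed, 179 up and 152 down. Endothelial genes rose again, 5 of 12 of them and 10 adjusted over the list alone, with a median of 0.76 (adjusted p = 1.69e-08). Oocyte growth genes fell by a median of -0.49, 2 of 22 of them and 10 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). The stress and immediate early list fell by a median of -0.55, with 1 of 15 genes down and 4 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). That call was lost with fry and without MLS repeat 3, where the median was -0.20, and the median was -1.14 without MLS repeat 2. Stroma and smooth muscle passed with a median of 0.48 and 2 of 17 genes up, pyrimidine synthesis with 0.22 and 0 of 15, and the ovulatory response with -0.55 and 0 of 4 (adjusted p = 0.110 to 0.268 with an estimated correlation). All 3 calls were lost without TLS repeat 3, where the medians were 0.43, 0.29 and -0.52. Pyrimidine synthesis was also lost without TLS repeat 1 (0.20), MLS repeat 2 (0.25) and MLS repeat 3 (0.25), and the ovulatory response without TLS repeat 2 (-0.44) and MLS repeat 3 (-0.43) and with no filter (-0.06). The count for MLS against TLS was 521 without TLS repeat 1, 203 without TLS repeat 3 and 108 without MLS repeat 1, and 3 when the variance was estimated from these 2 stages alone. Of the genes changed 54.1% rose, against 71.4% with median scaling.

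PREANTRAL was compared with MLS to ask what changes before the antrum forms. Inhba rose 17.9-fold, from 9.51 ± 0.71 to 13.68 ± 0.35 (adjusted p = 6.57e-06). Foxo1, a transcription factor of growing granulosa cells, rose 3.74-fold to 12.45 ± 0.10 (adjusted p = 2.64e-05), and Fshr rose 1.97-fold to 10.36 ± 0.14. Rnase1, a secreted ribonuclease, rose 8.52-fold. Gdf9 was 2.78-fold lower, at 14.09 ± 0.13 in MLS and 12.62 ± 0.25 in PREANTRAL (adjusted p = 2.64e-05). Bmp15 was 3.85-fold lower, Zp3 3.71-fold lower and H1f8, the oocyte linker histone, 3.99-fold lower. Tex19.2, a gene of the germ line, was 7.78-fold lower (adjusted p = 1.96e-06). Npb, a neuropeptide gene, was undetected in MLS and at least 5.46-fold higher in PREANTRAL. Amh (adjusted p = 0.358) did not pass, but did with PMD3 repeat 2 and TLS repeat 2 left out, which enter through the shared variance.

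Between MLS and PREANTRAL 1558 genes changed, 575 up and 983 down. Of 22 oocyte growth genes 21 fell, also adjusted over the list alone, with a median of -1.87 (adjusted p = 9.78e-28). Early germ cell regulators fell by a median of -0.74, 5 of 10 of them and 6 adjusted over the list alone (adjusted p = 0.0765 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, was 4.82-fold lower. Glycolysis and lactate genes rose by a median of 0.55, 5 of 15 of them and 8 adjusted over the list alone (adjusted p = 0.00642), and by 0.33 with undetected members at their bound. Pfkp, a rate-setting enzyme of glycolysis, rose 3.82-fold (adjusted p = 7.6e-06). In the gonadotropin response list 5 of 9 genes rose, also adjusted over the list alone, with a median of 0.70 (adjusted p = 0.165 with an estimated correlation). In the granulosa cell list 5 of 19 genes rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone, with a median of 0.47 (adjusted p = 0.343 with an estimated correlation). Stroma and smooth muscle genes fell by a median of -0.75, 7 of 17 of them and 11 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Surface epithelium genes fell by a median of -0.59, 3 of 8 of them and 4 adjusted over the list alone. Endothelial genes fell by a median of -0.45, 2 of 12 of them (adjusted p = 0.355 with an estimated correlation), a call lost without PREANTRAL repeat 3 (median -0.34), MLS repeat 1 (-0.37) or MLS repeat 3 (-0.41). Meiotic prophase genes had a median of -0.38 with 1 of 7 down (adjusted p = 0.103 with an estimated correlation), a call lost with median scaling (median -0.25), without background correction (-0.18), with the authors' values (-0.08) and without PREANTRAL repeat 2 (-0.29). The erythroid list rose by 1.27, 3 of 4 genes, also adjusted over the list alone. Of the genes changed, PREANTRAL against MLS, 36.9% rose, whereas median scaling gave 242 up of 1151.

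ANTRAL was compared with PREANTRAL to ask what changes when the antrum has formed under gonadotropin. Cyp11a1, which makes pregnenolone from cholesterol, rose 21.4-fold, from 7.47 ± 0.39 to 11.89 ± 0.15 (adjusted p = 2.94e-10). Star was undetected in every PREANTRAL array and was at least 6.33-fold higher in ANTRAL (adjusted p = 8.36e-14). Plin5, a lipid droplet coat gene, rose 57.9-fold (adjusted p = 2.25e-16), and its relative Plin4 was at least 84.2-fold higher. Scd1, a fatty acid desaturase, rose 19.8-fold to 10.46 ± 0.10. Amh was 13.7-fold lower, at 9.39 ± 0.37 in PREANTRAL and 5.62 ± 0.53 in ANTRAL (adjusted p = 8.65e-06). It was detected on only 2 of 3 ANTRAL arrays, so this fold rests partly on background. Rnase1 was 18.9-fold lower, and Esr2, an estrogen receptor of granulosa cells, was 4.55-fold lower. PREANTRAL repeat 2 carries the source name, day and diameter of an antral sample. It stayed in the group of its title, and Star was undetected in it.

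The count of genes changed was 2810, with 1319 up and 1491 down, and it was 2316 without PREANTRAL repeat 2. Of 13 cholesterol synthesis genes 12 rose, also adjusted over the list alone, with a median of 1.86 (adjusted p = 3.3e-12). Dhcr7, the last enzyme of that pathway, rose 8.16-fold and Mvd rose 4.89-fold. Of 15 fatty acid synthesis genes 12 rose and 13 adjusted over the list alone, with a median of 1.07 (adjusted p = 3.56e-08). Of 10 steroidogenesis genes 7 rose, also adjusted over the list alone, with a median of 1.74 (adjusted p = 3.2e-07). Glycolysis and lactate genes rose by a median of 0.53, 6 of 15 of them and 8 adjusted over the list alone. Leukocyte genes rose by a median of 0.90, 6 of 10 of them and 7 adjusted over the list alone, and by 0.76 with undetected members at their bound. Endothelial genes rose by 0.65, 5 of 12 of them and 8 adjusted over the list alone (adjusted p = 0.177 with an estimated correlation).

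Of 16 cell cycle genes 14 fell from PREANTRAL to ANTRAL and 15 adjusted over the list alone, with a median of -1.05 (adjusted p = 3.16e-08). Mcm2, a part of the replicative helicase, was 2.42-fold lower, at 10.63 ± 0.03 and 9.36 ± 0.05 (adjusted p = 8.18e-07), and Birc5, needed for chromosome segregation, was 2.29-fold lower. Oocyte growth genes fell further, 18 of 22 of them, with 19 down and 1 up adjusted over the list alone and a median of -1.47 (adjusted p = 0.134 with an estimated correlation). In the granulosa cell list 7 of 19 genes fell, also adjusted over the list alone, with a median of -0.32 (adjusted p = 0.264 with an estimated correlation). Theca and interstitial cell genes had a median of 0.36, with 4 of 10 up, also adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). Stroma and smooth muscle had a median of 0.43 with 5 of 17 up (adjusted p = 0.394 with an estimated correlation). Glutathione and peroxide genes had one of 0.15 with 7 of 21 up and 4 down, and cytosolic ribosomal protein genes one of -0.23 with 4 of 15 down (adjusted p = 0.115 and 0.236 with an estimated correlation). The calls of stroma and of ribosomal proteins were lost without PREANTRAL repeat 3 (medians 0.28 and -0.24), and that of ribosomal proteins also without PREANTRAL repeat 2 (-0.21) and ANTRAL repeat a (-0.20). That of glutathione was lost without PREANTRAL repeat 1 (0.17), PREANTRAL repeat 2 (0.17), ANTRAL repeat 1 (0.18) or ANTRAL repeat b (0.20), and with PMD3 repeat 2 and TLS repeat 2 left out. Of the genes changed, ANTRAL against PREANTRAL, 46.9% rose, against 64.3% with median scaling.

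ANTRAL was compared with PRIMARY for the net change from the first to the last stage of isolated follicles. The gonadotropin given for ANTRAL and the age of the mice go with this comparison and could not be separated from growth. Cyp11a1 rose 97.9-fold (adjusted p = 1.88e-13), Inhba 83.0-fold (adjusted p = 1.44e-09) and Fshr 2.32-fold (adjusted p = 0.000115). In PRIMARY, Cyp11a1 stood at 5.28 and was detected on only 2 of 3 arrays, so its fold rests partly on background. Cyp17a1, the theca enzyme of androgen synthesis, rose 15.6-fold to 12.36 ± 0.17, and its log2 fold change of 3.96 was 3.26 without PRIMARY repeat 2. Zp3 was 32.8-fold lower, Bmp15 24.2-fold lower and Gdf9 13.3-fold lower, the last with an adjusted p of 4.36e-12. Amh was 26.3-fold lower, with detection on 2 of 3 ANTRAL arrays. Ccnd2 (adjusted p = 0.915) did not pass. In all, 4681 genes changed, 2356 up and 2325 down, and 2423 changed by at least 2-fold.

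All 22 oocyte growth genes fell from PRIMARY to ANTRAL, also adjusted over the list alone, with a median of -4.33 (adjusted p = 1.4e-21). Early germ cell regulators fell by a median of -1.89, with 9 of 10 down, and with 9 down and 1 up adjusted over the list alone. Meiotic prophase genes fell by a median of -1.83, 5 of 7 of them and 6 adjusted over the list alone (adjusted p = 0.0756 with an estimated correlation), and by -1.33 with undetected members at their bound. Cell cycle genes fell by a median of -0.59, 8 of 16 of them, also adjusted over the list alone (adjusted p = 0.182 with an estimated correlation). All 12 endothelial genes rose, also adjusted over the list alone, with a median of 2.38 (adjusted p = 1.42e-08). Theca and interstitial cell genes had a median of 1.26, with 6 of 10 up, also adjusted over the list alone (adjusted p = 0.0756 with an estimated correlation), and of 1.03 at their bounds. Stroma and smooth muscle genes rose by a median of 1.48, 11 of 17 of them and 14 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Leukocyte genes rose by a median of 1.23, 7 of 10 of them and 8 adjusted over the list alone, and by 0.94 at their bounds. All 4 erythroid genes rose, also adjusted over the list alone, with a median of 1.57, or 1.24 at their bounds (adjusted p = 0.0756 with an estimated correlation), a call lost with the authors' values (median 0.37). Gonadotropin response genes rose by a median of 1.44, 7 of 9 of them and 8 adjusted over the list alone (adjusted p = 0.0672 with an estimated correlation).

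Because the series title concerns the metabolome, the metabolic lists were followed from PRIMARY to ANTRAL, where gonadotropin treatment goes with ANTRAL alone. The cholesterol synthesis medians were -0.07, -0.04 and 0.39 in the steps up to PREANTRAL, none passing, and 1.86 in the last step. Those of glycolysis and lactate were 0.19, 0.21, 0.55 and 0.53 over the same steps. Cholesterol synthesis rose by a median of 2.06, 12 of 13 genes, also adjusted over the list alone (adjusted p = 1.98e-08). Steroidogenesis rose by 2.36, 8 of 10 genes and 9 adjusted over the list alone (adjusted p = 8.2e-07). Fatty acid synthesis rose by 1.47, 13 of 15 genes, also adjusted over the list alone (adjusted p = 4.61e-06). Scd1 was undetected in PRIMARY and at least 39.6-fold higher in ANTRAL. Glycolysis and lactate genes rose by 1.04, 11 of 15, also adjusted over the list alone (adjusted p = 7.95e-05), with Hk2 up 4.73-fold. Fatty acid oxidation genes had a median of 0.48, with 8 of 15 up, and with 8 up and 1 down adjusted over the list alone (adjusted p = 0.182 with an estimated correlation). In the list of pyruvate dehydrogenase and TCA cycle 9 of 20 genes rose, also adjusted over the list alone, with a median of 0.37, and the list did not pass (adjusted p = 0.0521). It passed without PRIMARY repeat 3 (median 0.41), without ANTRAL repeat a (0.36), without background correction, with the authors' values, with no filter and with fry. Glutathione and peroxide genes did not pass either, with a median of 0.61, 11 of 21 up and 5 down, also adjusted over the list alone (adjusted p = 0.0562). They passed with median scaling (median 0.50), without PRIMARY repeat 2 (0.68) and without ANTRAL repeat a (0.66), and also without background correction, with the authors' values, with no filter and with fry.

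Of 29 lists 15 passed from PRIMARY to ANTRAL, and the following did not. Oxidative phosphorylation had a median of 0.11, with 10 of 38 genes up and 1 down, or 9 up and 1 down adjusted over the list alone. Purine synthesis and salvage had a median of 0.30, with 4 of 17 up and 2 down, also adjusted over the list alone. Pyrimidine synthesis had a median of -0.14, with 3 of 15 up and 3 down, also adjusted over the list alone. The pentose phosphate pathway had a median of -0.04 but a mean of 0.24, with 3 of 9 up and 1 down, also adjusted over the list alone. One-carbon and serine metabolism had a median of 0.11, with 4 of 11 up and 2 down, or 5 up and 2 down adjusted over the list alone. Amino acid transporters had a median of 0.21, a mean of -0.01 and a test direction of lower, with 5 of 17 up and 6 down, also adjusted over the list alone. Cytosolic ribosomal protein genes had a median of -0.10, with 1 of 15 down, or 0 adjusted over the list alone. The ovulatory response list had a median of 1.06 with 2 of 4 up, and the list of apoptosis and atresia had a median of 0.31 with 2 of 8 up and 2 down, both also adjusted over the list alone. Granulosa cell genes had a median of 0.21 with 8 of 19 up and 5 down, surface epithelium one of 0.93 with 5 of 8 up and 3 down, and the stress and immediate early list one of -0.09 with 6 of 15 up and 3 down. Oxidative phosphorylation passed with the authors' values and with fry, and purine synthesis, ribosomal proteins, the ovulatory response, apoptosis and surface epithelium passed with fry alone. Among 203 tests of lists, 79 passed, and 29 of them passed with an estimated correlation as well. A list's adjusted p printed without naming an estimated correlation rests on the preset one of 0.01, which treats members as nearly independent. Very small values therefore overstate the evidence where members vary together.

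**Figure D4:**
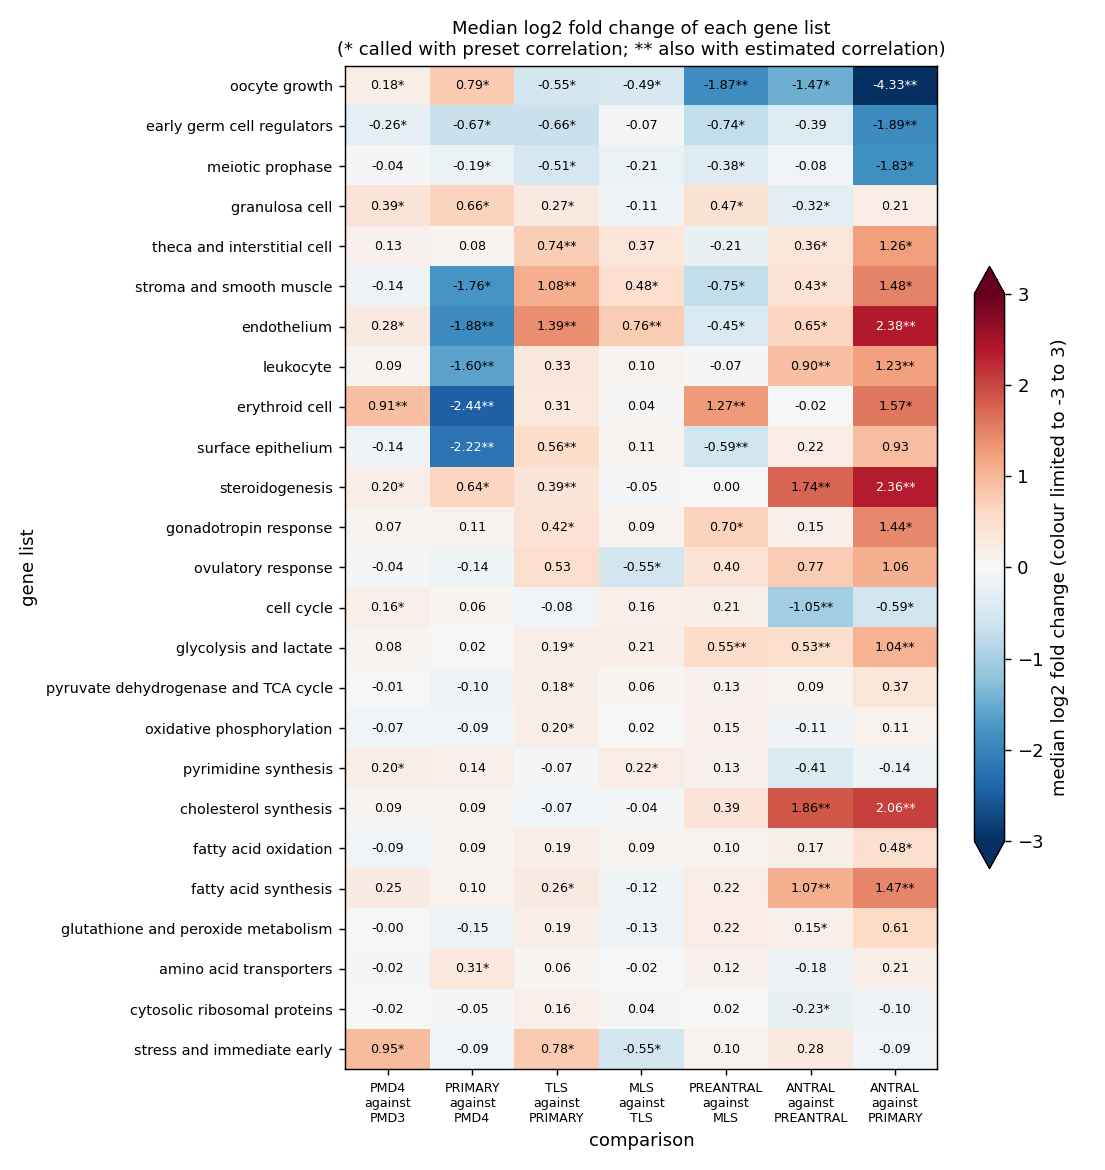
Median log2 fold change (colour, limited to the range from -3 to 3) of 25 gene lists (rows) in the 7 comparisons (columns), with * for an adjusted p under 0.05 with the preset correlation and ** where an estimated correlation passed as well. The oocyte growth list has a median of -4.33 for ANTRAL against PRIMARY, and cholesterol synthesis one of 2.06.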

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

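The alternative that left out 2 deviating arrays together, the repeat block on the authors' values and the form of the repeat block without the unnumbered antral arrays were tests chosen only after the results were seen. In no called result did the direction of the test reverse where it could. With an estimated correlation the direction cannot change. That of fry was not compared, so lists passing with fry have no checked direction. However, 3 medians of called lists changed sign without passing. With median scaling, gene list oxidative phosphorylation, TLS against PRIMARY, went from 0.20 to -0.07 and gene list pyruvate dehydrogenase and TCA cycle, TLS against PRIMARY, from 0.18 to -0.07. With no filter, gene list meiotic prophase, PRIMARY against PMD4, went from -0.19 to 0.01. Values that had not passed changed sign too, such as log2 fold change of Ccnd2, TLS against PRIMARY, from 0.42 to -0.34 and log2 fold change of Foxl2, TLS against PRIMARY, from 0.27 to -0.51, both without TLS repeat 2. Over all alternatives 6984 values of named genes kept their side of the threshold, 366 lost it and 45 gained it. Of the gene list results 2772 kept their side, 132 lost it and 83 gained it. The losses of lists include 50 under the estimated correlation and 4 with the fry test.

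Counts of genes stayed within 1.5 times the reported count in 244 cases and moved further in 31. No background correction, the authors' values, no filter, the strict filter, the mean of a gene's probes, and trend and robust moderation moved none of the 8 counts further. An adjusted p under 0.01 gave 31 genes for PMD4 against PMD3 in place of 128, 298 for TLS against PRIMARY in place of 733, 87 for MLS against TLS in place of 331, 909 for PREANTRAL against MLS in place of 1558 and 1819 for ANTRAL against PREANTRAL in place of 2810, as a stricter threshold must. The test against a 1.2-fold change, stricter by construction as well, gave 22 for PMD4 against PMD3, 1967 for PRIMARY against PMD4 in place of 3169, 244 for TLS against PRIMARY, 58 for MLS against TLS, 794 for PREANTRAL against MLS and 1582 for ANTRAL against PREANTRAL. With only the 6 arrays of a comparison, and so fewer arrays behind the variance, 51 genes changed for PMD4 against PMD3, 167 for TLS against PRIMARY and 3 for MLS against TLS. Array weights gave 386 for PMD4 against PMD3, 4827 for PRIMARY against PMD4 and 193 for MLS against TLS. They gave PMD3 repeat 2 a weight of 0.211 and TLS repeat 2 one of 0.216, against 3.67 for PRIMARY repeat 2. Median scaling, which is centred on signal near the background, gave 217 for MLS against TLS, and the cause was not tested. Leaving out the 2 deviating arrays together gave 77 for PMD4 against PMD3.

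With each array left out in turn, the count ran from 32 to 210 for PMD4 against PMD3, from 2580 to 3421 for PRIMARY against PMD4, from 381 to 1070 for TLS against PRIMARY and from 108 to 521 for MLS against TLS. It ran from 1075 to 1755 for PREANTRAL against MLS, from 2212 to 3078 for ANTRAL against PREANTRAL and from 4096 to 4939 for ANTRAL against PRIMARY. Genes differing over the 7 stages numbered 6382 to 6971. The counts of PMD4 against PMD3, TLS against PRIMARY and MLS against TLS thus depended strongly on which arrays were kept. For PMD4 against PMD3, leaving out any array of these stages lowered the count. A stage that loses an array also gives the test less power, and how much of the moves this explains was not tested. An array outside a comparison enters through the shared variance.

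The replicate block, with the repeat number as a term of the model, gave 118, 3224, 759, 347 and 1599 genes for the 5 comparisons without ANTRAL, in order of stage. On the authors' values, where every antral sample has a number, the replicate block gave 147, 3161, 828, 398, 1554, 2763 and 4676 genes for the 7 comparisons, and 6598 over all stages. Of 51 pairs of arrays with the same number in different stages, 12 deviated from their stages with a correlation over 0.1, and the median was 0.0230. For pairs with different or unknown numbers the median was -0.00567. The numbers therefore do not pair the samples throughout. The files do not name the slides, so no block for them was run.

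The genes called under an alternative were not always the same. For the result genes changed, PMD4 against PMD3, 75 of the 144 genes called with the authors' values were among the reported 128, and 90 of the 122 called with median scaling were. For the result genes changed, PRIMARY against PMD4, 2847 of the 3099 genes called with the authors' values were shared. Signal over background limits the dim genes: a gene near the background has a compressed fold change, and one undetected in a stage has only a bound.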

Other observations

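The tests of swapped samples, of cells from whole ovaries, of tissue on the TLS follicles, of scaling and of gene families, and the spreads of the oocyte genes' falls and of sibling probes, were chosen only after the results were seen. The test on sibling probes, the test of dilution and the splits of the arrays were not.

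Genes whose symbols share their first letters were tested as families, to ask which groups of related genes move together. Of 323 families with at least 5 genes, tested in 7 comparisons each, 35 results passed, and 0 of these 35 passed with an estimated correlation. The families and genes named here were chosen after their values were seen. All 6 Tcl genes, relatives of a cofactor of the kinase Akt, rose from PMD4 to PRIMARY with a median of 2.00 (adjusted p = 8.48e-05), and Tcl1b3 rose 7.95-fold. The same 6 genes fell from MLS to PREANTRAL with a median of -1.74 (adjusted p = 6.74e-08). From PRIMARY to ANTRAL they fell by a median of -3.95. Of 6 Nlrp genes, which include genes of the oocyte's cortical complex, 5 fell from MLS to PREANTRAL with a median of -1.68, and Nlrp9b did not pass. Median scaling, no background correction and the authors' values gave the same directions for these 3 results and for the Nlrp genes. Probes of such close relatives were not checked for binding to each other's transcripts.

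Of 8 Mcm genes, which encode parts of the replication machinery, 7 fell from PREANTRAL to ANTRAL with a median of -1.09 (adjusted p = 0.000891), and Mcm9 did not pass. Some of them also sit in the cell cycle list. All 6 Cdca genes, named for their tie to cell division, fell in the same comparison with a median of -0.92. Of 27 collagen genes 15 fell and 1 rose from PMD4 to PRIMARY, with a median of -1.02. These 3 directions were the same under median scaling, without background correction and with the authors' values. The estimated correlation gave adjusted p-values of 0.581 for the 3 results.

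Pebp4 went up and down between stages, with levels of 7.09 in PRIMARY, 4.86 in TLS, 8.34 in MLS, 8.02 in PREANTRAL and 4.57 in ANTRAL. It was detected on no TLS and no ANTRAL array.

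PMD3 repeat 2 and TLS repeat 2 deviated from their stages in the same way, across genes with a correlation of 0.721 between the deviations. An effect on single probes, as from labelling, hybridization or RNA integrity, was tested on 1490 genes with 2 probes detected on all arrays, since a change in a gene's RNA should show on both probes. The deviations of the 2 arrays correlated at 0.811 on the same probe and at 0.226 between sibling probes, whereas the difference of PREANTRAL and MLS gave 0.708 and 0.618. The quotient of the ratios was 0.319 (95% bootstrap interval 0.243 to 0.392), which is consistent with an effect on single probes. A swap of the samples is argued against, as TLS repeat 2 had a mean correlation of 0.965 with the other TLS arrays and of 0.921 with PMD3. No biological explanation was tested.

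Markers of cells outside the follicle were low in PRIMARY. From PMD4 to PRIMARY 5 of 5 lists fell (stroma, endothelium, leukocytes, surface epithelium, erythroid cells), but these lists are the pattern itself, so their fall tests no cause. Cells that whole ovaries hold and isolated follicles lack, and a change with stage, cannot be told apart here, because tissue and stage change together. For the later rise in TLS, the endothelial median exceeded the leukocyte one by 1.06 (95% bootstrap interval 0.32 to 1.98), but 8 of 10 leukocyte genes were undetected in PRIMARY or TLS, so the comparison decides nothing. More outside tissue of every kind on the TLS follicles and a growing theca layer with its vessels therefore cannot be told apart here.

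Oocyte growth genes were lower in ANTRAL than in PRIMARY. The fall did not hinge on the choice among the scalings tried, as the median was -3.71 under the weaker of median scaling and the authors' values. Both settings centre the arrays much alike, with a median of all genes of -0.03 and 0.01 against 0.02. The test could therefore hardly have come out otherwise, and it decides nothing about scaling as a cause. Dilution of unchanged oocyte RNA by the RNA of other cells would let every gene lose the same part of its fall by MLS, and over 21 members that part ran from 13.6% (Bmp15) to 42.7% (Khdc3). The parts differed beyond their standard errors (heterogeneity p of 0.000134), but these errors hold the spread between arrays and leave out differences between probes. Between sibling probes the SD was 6.47% over 31 genes falling over 4-fold and 2.61% over 12 falling over 8-fold. The SD of the members' parts, 8.08%, missed the margin set before the test, 2 times the mean standard error of 5.07%. By that margin dilution and a loss of transcripts in the oocyte cannot be told apart here, and the unequal falls (Btg4 fell by 1.91 and H1f8 fell by 5.31 on the log2 scale, SD 0.82 against 0.28 between sibling probes) do not settle it, as saturation of bright probes and expression in other cells were not excluded.

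Other splits of the arrays were compared with the real one. For genes differing over the 7 stages, 1 of 100 random groupings, the real one with 6735 genes, gave as many, and the highest other gave 934. That share is the smallest that 100 groupings can reach, so random grouping alone is unlikely to give the count. The test cannot tell stage from other differences between the samples, as the labels do not show separate animals. For the comparisons, the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. Every other split mixes arrays of both stages, so a difference between them, of any origin, adds to the spread. Low counts in the other splits are therefore built in and decide nothing about the cause. The real count and the highest other were 128 and 1 for PMD4 against PMD3, 3169 and 1 for PRIMARY against PMD4, and 733 and 1 for TLS against PRIMARY. They were 331 and 2 for MLS against TLS, 1558 and 1 for PREANTRAL against MLS, 2810 and 1 for ANTRAL against PREANTRAL, and 4681 and 0 for ANTRAL against PRIMARY.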
